A study of Mus musculus with 51 samples.

How the data were processed

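Total RNA of mouse ventral prostate was extracted with Trizol, converted to biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels. The 51 arrays form 13 groups by genotype (11 arrays of wild type and 40 of AKT1 transgenic mice), treatment (placebo or RAD001) and time. The values deposited by the authors are linear probe set intensities, 1 per array for 22626 probe sets, in 2 tables. They had been scaled between arrays by a method not given in the sources used here. Array medians lay from 91.6 to 109.3 in the table of 12 h, 48 h and 15 d and from 98.1 to 110.4 in the table of 6 d and 9 d, and the quartiles were close without being equal. The software that made the intensities, the dose of RAD001 and the order of hybridisation were not given in the sources used here. No column of values per array was left unused.

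Values under 16 were set to 16 and log2 was taken, which affected from 10.3% to 15.8% of the values of an array in the larger table and from 9.2% to 14.1% in the smaller. Arrays were used as deposited, since their log2 medians differed by less than the limit set beforehand for a further normalisation. Probe sets whose mean log2 lay below the 40th percentile of the table were left out, and 1 probe set per gene was kept, that with the highest mean. Of the probe sets 20380 have 1 gene symbol, 691 have several and 1555 have none, and those without a single symbol were tested but not named. Of the larger table, 3 values of the probe sets for Cdx2 and Gja5 lay beyond any scanner range, and both probe sets were left out there. Of the smaller table, 28 values on 1 array were just below 0 and took the floor. This left 9627 features (8496 named) and 9345 features (8227 named). Rps6kb1, the gene of a kinase that mTOR activates, was too dim to be tested in either table.

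The groups, comparisons, gene lists, tests and most of the other settings tried were fixed before the data were examined. Each table was fitted in limma 3.58.1 under R 4.3.3 with 1 mean per group over all its arrays and moderated variances with an intensity trend, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The genotype contrast was transgenic minus wild type under placebo, averaged over 12 h, 48 h and 15 d. RAD001 was compared with transgenic placebo of the same time, and 6 d and 9 d were averaged because each day has 1 placebo array. F-tests asked whether the genotype or the RAD001 effect differed between 12 h, 48 h and 15 d. Genes called between genotypes were taken from the 2 other times when their RAD001 change was read at the time tested. The overlap of calls between times was compared with the product of the numbers called over the number tested, for each direction.

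The 30 gene lists cover metabolic and growth pathways and markers of the cell types that a prostate sample could hold. They were tested with camera at a correlation between genes of 0.01, with adjustment over all 144 tests, and again with an estimated correlation and with fry. Fry tests whether the genes of a list move on balance in 1 direction, without comparing them with other genes. A list needed 3 measured members, which 1 list missed in the larger table and 2 lists in the smaller. Counts of members are given over all genes tested and adjusted over the list alone. A list score per array is the mean deviation of its members from their mean over the table.

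The named genes follow a rule fixed beforehand. For each of the 5 main comparisons it takes the 10 largest rises and falls among called genes with a single symbol, up to 4 members with the smallest p of each list described, and Akt1, Mtor, Rps6kb1, Eif4ebp1, Pbsn, Slc2a1 and Vegfa. For each test of an effect by time it takes the 5 genes with the smallest p. Any of these could be left out of the text.

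Settings fixed beforehand were no filter on dim probe sets or one at the 60th percentile, a floor of 64, quantile normalisation, median scaling, all probe sets tested apart, array weights, a fit of the compared groups only, the replicate number as a block, each day alone, an unadjusted p under 0.01 for overlaps, a split of the placebo arrays, and leaving out each array in turn. Others were chosen after seeing the data. One left out arrays with over 500 probe sets at exactly 0, which are transgenic placebo replicates 8 and 9 of 15 d, RAD001 replicate 1 of 6 d and RAD001 replicate 3 of 9 d. A first rule, on the correlation with other arrays, had taken 4 arrays including a RAD001 array of 15 d and was replaced. Others used the pair of array sets seen at 15 d along the first principal component (26.5% of the variance of the larger table), as a block or apart, or took the genotype from 12 h and 48 h alone.

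The procedure was tested on simulated data with 200 changed genes. Changes of 1 log2 unit were recovered in 88.7% of cases for the genotype, 74.2%, 73.1% and 84.6% for RAD001 at 12 h, 48 h and 15 d, and 52.6% at 6 d and 9 d. Without any change limma called 0 features, and the share of genotype genes with a RAD001 change of the opposite sign was 50.4%, 51.5% and 49.0%. The simulated noise was drawn for each gene apart, without correlation between genes, array sets or outlying arrays. Other splits of the real arrays gave such shares up to 80%, 71% and 71.6% at 12 h, 48 h and 15 d. The simulated values therefore do not show how far chance can move the real ones. No pair of arrays held identical values, and the highest correlation between 2 arrays was 0.987 in the larger table and 0.989 in the smaller. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.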

Results

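RNA of the ventral prostate was read on 51 Affymetrix arrays from mice of the FVB strain that were wild type or carried an AKT1 transgene. AKT1 is a kinase that acts upstream of mTOR, and RAD001 (everolimus) inhibits mTOR. The stated aim was to separate markers of drug action from markers of response. Wild type mice received placebo and gave 4 arrays at 12 h, 4 at 48 h and 3 at 15 d. Transgenic mice received placebo (4 arrays at 12 h, 5 at 48 h, 1 at 6 d, 1 at 9 d and 7 at 15 d) or RAD001 (5 arrays at 12 h, 4 at 48 h, 3 at 6 d, 4 at 9 d and 6 at 15 d). The dose was not given in the sources used here. The 12 h, 48 h and 15 d arrays came as 1 table of 42 arrays and the 6 d and 9 d arrays as another of 9, and each table was tested on its own. The median intensity of an array lay between 91.6 and 109.3 in the larger table and between 98.1 and 110.4 in the smaller. Changes are log2 values with their standard error (SE). The p-values measure the spread between arrays, which the labels call biological replicates, and the number of arrays limits the precision.

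The first comparison asked which transcripts differed between transgenic and wild type prostate under placebo. Transgenic glands had more RNA of glycolytic, hypoxia-responsive and lysosomal genes and less of smooth muscle genes. Psca, a surface antigen of prostate epithelium, was 25.6-fold higher (log2 4.68 ± 0.69), and the acute-phase gene Saa2 was 16.3-fold higher (4.02 ± 0.46). The chemokine Cxcl15 rose by 2.97 ± 0.40, the calcium-binding protein gene Tesc by 2.20 ± 0.21, the keratin gene Krt23 by 1.98 ± 0.17 and the stress transcription factor gene Atf3 by 1.96 ± 0.19. Th, which encodes tyrosine hydroxylase, fell by 2.80 ± 0.38, the water channel gene Aqp5 by 2.25 ± 0.31, and the sulphate donor synthase gene Papss2 fell by 1.78 ± 0.20. The chemokine receptor gene Ackr3 fell by 1.74 ± 0.26, the surface marker gene Prom1 by 1.63 ± 0.19 and the nuclear receptor gene Nr2f1 fell by 1.52 ± 0.21.

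Of 14 measured glycolysis genes 9 rose and 0 fell (10 rose when adjusted over the list alone), with a median of 0.79. Their score lay above the wild type mean of the same time in 4 of 4, 5 of 5 and 5 of 7 transgenic placebo arrays at 12 h, 48 h and 15 d. The triosephosphate isomerase gene Tpi1 rose by 1.31 ± 0.09, the phosphofructokinase gene Pfkl by 1.49 ± 0.11, the aldolase gene Aldoa by 1.09 ± 0.08 and the phosphoglycerate kinase gene Pgk1 by 1.13 ± 0.09. Among 18 hypoxia targets outside glycolysis 9 rose and 1 fell (10 and 1 adjusted over the list alone). Bnip3, a mitophagy gene, rose by 1.88 ± 0.11, the ER oxidase gene Ero1a by 1.85 ± 0.18, the lysyl hydroxylase gene Plod2 by 0.68 ± 0.08 and the prolyl hydroxylase gene Egln3 by 0.45 ± 0.08. The geometric mean of the Bnip3 intensity at 12 h was 338 in wild type and 1480 in transgenic placebo arrays (log2 8.4 ± 0.14 and 10.53 ± 0.29, SD, n = 4 each). Of 21 lysosome and autophagy genes 13 rose and 1 fell (14 and 3 adjusted over the list alone), among them the hexosaminidase gene Hexa (0.91 ± 0.10), the cathepsin gene Ctsd (0.78 ± 0.09) and the membrane protein gene Lamp1 (0.33 ± 0.04). Lamp2 rose by 0.53 ± 0.06, although its 4 probe sets ranged from -0.11 to 0.81. In cholesterol synthesis 7 of 19 members rose and 0 fell, the same as adjusted over the list alone, led by Fdft1 (1.59 ± 0.13), Cyp51 (1.49 ± 0.19), Dhcr7 (1.43 ± 0.26) and Fdps (1.04 ± 0.12). The median of that list was 0.10, and its call was lost with an estimated correlation (adjusted p = 0.203).

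Markers of the cell types of the gland moved with these groups. Of 18 luminal epithelial markers 9 rose and 1 fell, the same as adjusted over the list alone. Krt8 rose by 0.91 ± 0.09, the cadherin gene Cdh1 by 0.82 ± 0.09 and the protease inhibitor gene Spint1 by 0.63 ± 0.07, and the call of the list gave an adjusted p = 0.0694 with an estimated correlation. Of 13 smooth muscle genes 11 fell and 0 rose (12 fell adjusted over the list alone), with a median of -0.93. The filamin gene Flna fell by 1.10 ± 0.12, Tpm2 by 0.93 ± 0.11, Tagln by 0.91 ± 0.09 and the actin gene Acta2 fell by 0.72 ± 0.08. The score of this list was lower than the wild type mean of the same time in 4 of 4, 5 of 5 and 7 of 7 transgenic placebo arrays at 12 h, 48 h and 15 d. Of 15 fibroblast and matrix genes 9 fell and 0 rose, the same as adjusted over the list alone (adjusted p = 0.203 with an estimated correlation). The growth factor gene Igf1 fell by 1.15 ± 0.13, the collagen gene Col1a2 by 0.96 ± 0.14 and the proteoglycan gene Dcn by 0.82 ± 0.10. Of 3 probe sets of Igf1 tested apart 2 were called (-1.15 to -0.12). Basal epithelial genes were not called as a list by camera (adjusted p = 0.112), with 5 of 11 lower and 0 higher (5 and 1 adjusted over the list alone). Fry called this list down (adjusted p = 3.66e-05). Trp63, a basal cell transcription factor, fell by 0.74 ± 0.08, Krt5 by 0.49 ± 0.09 and the integrin gene Itga6 fell by 0.49 ± 0.09. Of 24 ribosomal protein and elongation factor genes 10 fell and 0 rose (11 fell adjusted over the list alone), with small changes such as -0.32 ± 0.05 for Rps9 and -0.21 ± 0.04 for Rpl10a (adjusted p = 0.262 with an estimated correlation).

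In limma with Benjamini-Hochberg adjustment 3222 of 9627 features were called, 1369 higher and 1853 lower in transgenic glands averaged over 12 h, 48 h and 15 d. At least 2-fold changes numbered 99 up and 57 down. Each time alone gave 1987, 2564 and 1920 features. At 15 d all wild type arrays lay in array set A, described below, and most transgenic placebo arrays in set B. Genotype and array set are thus partly confounded there. Without set B the averaged contrast called 3294 features, and from 12 h and 48 h alone 3136. Wild type arrays differed between 12 h and 48 h in 1650 genes and transgenic placebo arrays in 0. For the wild type arrays time and handling cannot be told apart. The probe set used for Akt1 had a change of 0.17 ± 0.08 (adjusted p = 0.0932), while the other probe set of the gene gave 0.88 and was called. Whether either reads the transgene is not given in the sources used here. Eif4ebp1, a target of mTOR that restrains translation, fell by 0.32 ± 0.10. Mtor (-0.27 ± 0.26), the probasin gene Pbsn (-0.16 ± 0.15), Slc2a1 (0.24 ± 0.28) and Vegfa (0.02 ± 0.08) were not called. With all probe sets tested apart, 2 of 3 were called for Slc2a1 (0.24 to 1.26). For Vegfa (0.02 to 0.40) and Mtor (-0.31 to -0.27) 1 of 2 was called. The Mtor value includes 15 d placebo replicate 9, which lay at the floor of 4.0 (nearest array 7.74). Without 2 placebo arrays of 15 d with many values at exactly 0 (replicates 8 and 9) Slc2a1, the glucose transporter gene, was called at 0.44 (adjusted p = 3.02e-06).

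RAD001 at 12 h addressed the early effect of the drug in transgenic glands. Glycolytic and cholesterol synthesis genes were lower and clock genes were higher than under placebo. Pfkl fell by 1.05 ± 0.19, the peptidase gene Prep fell by 1.01 ± 0.18, the tubulin gene Tubb4b by 0.95 ± 0.17 and the replication clamp gene Pcna fell by 0.75 ± 0.12. The cholesterol transporter gene Abca1 rose by 1.07 ± 0.17 and the phosphodiesterase gene Pde4b by 1.14 ± 0.22. Of 22 named genes called at 12 h these 6 kept their calls whichever single array was left out, and beside the others stands the highest adjusted p of those fits. With all probe sets tested apart, 1 of 2 was called for Pfkl (-1.05 to -0.75), Abca1 (0.40 to 1.07) and Pde4b (0.59 to 1.14). For Tubb4b 1 of 4 was called (-0.95 to -0.49).

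Of 14 glycolysis genes 5 fell and 0 rose at 12 h (8 fell adjusted over the list alone), with a median of -0.59. Their score lay below the placebo mean in 5 of 5 RAD001 arrays. Tpi1 fell by 0.81 ± 0.15, Aldoa by 0.65 ± 0.14 and the hexokinase gene Hk2 by 0.68 ± 0.17, and without placebo replicate 2 their adjusted p was 0.0503, 0.075 and 0.112. In cholesterol synthesis 1 of 19 fell (5 adjusted over the list alone), with a median of -0.43. That gene was Fdps, the farnesyl diphosphate synthase gene, which fell by 1.0 ± 0.20 (adjusted p = 0.054 without placebo replicate 2). The values of Cyp51 (-1.17 ± 0.32), Ebp (-0.27 ± 0.09) and Fdft1 (-0.60 ± 0.21) did not pass. Among 18 hypoxia targets only Bnip3 passed, as it also did adjusted over the list alone. It fell by 0.79 ± 0.18 and lay below the placebo mean in 4 of 5 arrays (adjusted p = 0.113 without placebo replicate 2). This list was called, with an adjusted p = 0.0675 with an estimated correlation. Of 13 clock genes 3 rose and 0 fell (4 rose adjusted over the list alone), with a median of 0.37. The nuclear receptor gene Nr1d2 rose by 0.94 ± 0.19, the repressor gene Cry2 by 0.68 ± 0.18 and the transcription factor gene Tef by 0.60 ± 0.16. Their adjusted p was 0.0528 without placebo replicate 2, 0.187 without placebo replicate 1 and 0.173 without RAD001 replicate 5. The array titles give no hour of the day at which the glands were collected. Whether the treatments differed in it was therefore not tested for these clock genes.

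Other lists were called at 12 h without holding under an estimated correlation. Ribosome biogenesis had 1 of 25 members lower (2 adjusted over the list alone), the small nucleolar protein gene Nhp2 (-0.47 ± 0.12; adjusted p = 0.126 without RAD001 replicate 2). The list had a median of -0.18 and an adjusted p = 0.198 with an estimated correlation. In the cell cycle list only Pcna passed of 20 (adjusted p = 0.123 with an estimated correlation), the same as adjusted over the list alone. Oxidative phosphorylation was called down with 0 of 25 members passing (3 fell adjusted over the list alone; adjusted p = 0.115 with an estimated correlation). Its median was -0.14, with Ndufa9 at -0.26 ± 0.08 and Cycs at -0.38 ± 0.13. Of 13 smooth muscle genes 1 rose (3 adjusted over the list alone), with a median of 0.51 and a score above the placebo mean in 5 of 5 RAD001 arrays (adjusted p = 0.173 with an estimated correlation). That gene was Tagln (0.64 ± 0.15; adjusted p = 0.142 without placebo replicate 1). Of 19 FOXO targets 1 rose (2 rose and 1 fell adjusted over the list alone), and the list had an adjusted p = 0.198 with an estimated correlation. Fbxo32, a ubiquitin ligase gene induced by FOXO factors, rose by 1.28 ± 0.30 (adjusted p = 0.0973 without placebo replicate 1).

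At 12 h limma with Benjamini-Hochberg adjustment called 142 of 9627 features, 62 higher and 80 lower, and 13 by at least 2-fold. Median scaling gave 158 features (34 higher, 124 lower), array weights 857 (513 and 344, so that most were higher) and the compared groups alone 78. Of 22 named genes called 15 lost the call in some alternative. The largest rises were those of Ackr3 (1.84 ± 0.44) and Nr2f1 (1.53 ± 0.36), for which the adjusted p was 0.131 and 0.128 without placebo replicate 1. Leaving out 1 array gave 43 features (placebo replicate 1), 31 (placebo replicate 2), 66 (RAD001 replicate 2), 84 (RAD001 replicate 3) or 71 (RAD001 replicate 5). Fam3b, a secreted protein gene, fell by 1.03 ± 0.23 (adjusted p = 0.062 without placebo replicate 2), and the serine synthesis gene Psat1 fell by 0.80 ± 0.21 (0.154 without RAD001 replicate 5). Man1a rose by 1.17 ± 0.26 (0.108 without placebo replicate 2). Akt1 (-0.10 ± 0.13), Mtor (0.18 ± 0.44), Eif4ebp1 (0.29 ± 0.16), Pbsn (0.20 ± 0.26), Slc2a1 (-0.61 ± 0.47) and Vegfa (-0.04 ± 0.13) were not called. With all probe sets tested apart, 1 of 3 was called for Slc2a1 (-0.93 to -0.61). Without the 15 d arrays with many zeros 232 features were called, Slc2a1 among them (-0.61, adjusted p = 0.00177). In 5 of 5 RAD001 arrays of 12 h Slc2a1 lay below every placebo array of that time. Its SE is taken over all arrays of the table, among them 15 d placebo replicate 9 at the floor of 4.0 (nearest 8.16).

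RAD001 at 48 h was compared with placebo of the same time. Glycolytic, hypoxia-responsive, cholesterol synthesis and lysosomal genes were lower. Cyp51, the lanosterol demethylase gene, was 4.50-fold lower (-2.17 ± 0.32), Bnip3 fell by 1.41 ± 0.18, Fdps by 1.37 ± 0.20 and the lysosomal glucuronidase gene Gusb by 1.33 ± 0.27. The largest rise was that of the epithelial envelope gene Sprr1a, 11.7-fold (3.55 ± 0.71). Th rose by 2.56 ± 0.64 (adjusted p = 0.084 without RAD001 replicate 5), the lipid transfer gene Pltp rose by 1.24 ± 0.19 and the ER chaperone gene Dnajb9 by 1.25 ± 0.27.

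Of 14 glycolysis genes 8 fell and 0 rose at 48 h, the same as adjusted over the list alone, with a median of -0.82. The aldolase gene Aldoc fell by 1.21 ± 0.16, Pgk1 by 0.98 ± 0.15, Tpi1 by 0.94 ± 0.15 and Aldoa by 0.70 ± 0.14. Pgk1, Tpi1 and Bnip3 lay below the placebo mean in 4 of 4 RAD001 arrays. Of 18 hypoxia targets 3 fell, the same as adjusted over the list alone, including Plod2 (-0.90 ± 0.13) and Mxi1 (-0.47 ± 0.10). In cholesterol synthesis 5 of 19 fell and 0 rose (9 fell adjusted over the list alone), with a median of -0.37. The squalene synthase gene Fdft1 fell by 1.06 ± 0.21 and the sterol reductase gene Tm7sf2 by 0.73 ± 0.15. Of 21 lysosome and autophagy genes 3 fell (7 adjusted over the list alone). Lamp1 fell by 0.27 ± 0.07, the proton pump gene Atp6v1a by 0.50 ± 0.12 (adjusted p = 0.121 without RAD001 replicate 4) and Lamp2 by 0.47 ± 0.09, with probe sets of Lamp2 from -0.47 to 0.24.

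Markers of stroma and epithelium moved beside them at 48 h. Of 13 smooth muscle genes 2 rose (5 adjusted over the list alone), with a median of 0.56 and an adjusted p = 0.164 with an estimated correlation. They were Cnn1 (1.07 ± 0.29) and the myosin kinase gene Mylk (0.83 ± 0.21), with an adjusted p of 0.148 and 0.103 without RAD001 replicate 5, and another probe set of Mylk gave -0.08. Of 15 fibroblast genes 2 rose, the same as adjusted over the list alone (adjusted p = 0.262 with an estimated correlation), Dcn by 0.72 ± 0.18 and Igf1 by 0.97 ± 0.22 (adjusted p = 0.0513 without RAD001 replicate 5; another probe set gave -0.16). Of 18 luminal markers 1 fell (2 adjusted over the list alone; adjusted p = 0.203 with an estimated correlation), Krt8 by 0.67 ± 0.15 (adjusted p = 0.0613 without RAD001 replicate 4). In oxidative phosphorylation 1 of 25 fell (2 adjusted over the list alone; adjusted p = 0.0523 with an estimated correlation), Uqcrfs1 by 0.46 ± 0.11 (adjusted p = 0.0657 without RAD001 replicate 1). In the cell cycle list Pcna alone fell, by 0.42 ± 0.12 (adjusted p = 0.107 without RAD001 replicate 1), the same as adjusted over the list alone, and the list had an adjusted p = 0.0571 with an estimated correlation. Of 19 FOXO targets 2 rose, the same as adjusted over the list alone, Fbxo32 by 1.12 ± 0.30 and Igfbp5 by 0.60 ± 0.17. Their adjusted p was 0.0966 and 0.12 without RAD001 replicate 5, another probe set of Igfbp5 gave -0.26, and the list had an adjusted p = 0.0694 with an estimated correlation.

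At 48 h limma with Benjamini-Hochberg adjustment called 341 of 9627 features, 194 higher and 147 lower, and 37 by at least 2-fold. The compared groups alone gave 233 (110 higher, 123 lower) and array weights 578. Of 31 named genes called 12 lost the call without some single array and 10 in some other alternative. Leaving out 1 array gave 201 features (placebo replicate 3), 194 (placebo replicate 4), 223 (RAD001 replicate 4) or 147 (RAD001 replicate 5, 69 higher and 78 lower). Fam3b fell by 1.26 ± 0.23, and Nr2f1 rose by 1.21 ± 0.36 (adjusted p = 0.193 without RAD001 replicate 5). Akt1 (0.09 ± 0.13), Mtor (0.31 ± 0.44), Eif4ebp1 (0.06 ± 0.16), Pbsn (0.14 ± 0.26), Slc2a1 (-0.80 ± 0.47) and Vegfa (-0.21 ± 0.13) were not called. Without the 15 d arrays with many zeros, which enter the SE of every time, Slc2a1 was called at -0.80 (adjusted p = 3.47e-05). In 4 of 4 RAD001 arrays of 48 h it lay below every placebo array of that time.

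**Figure D1:**
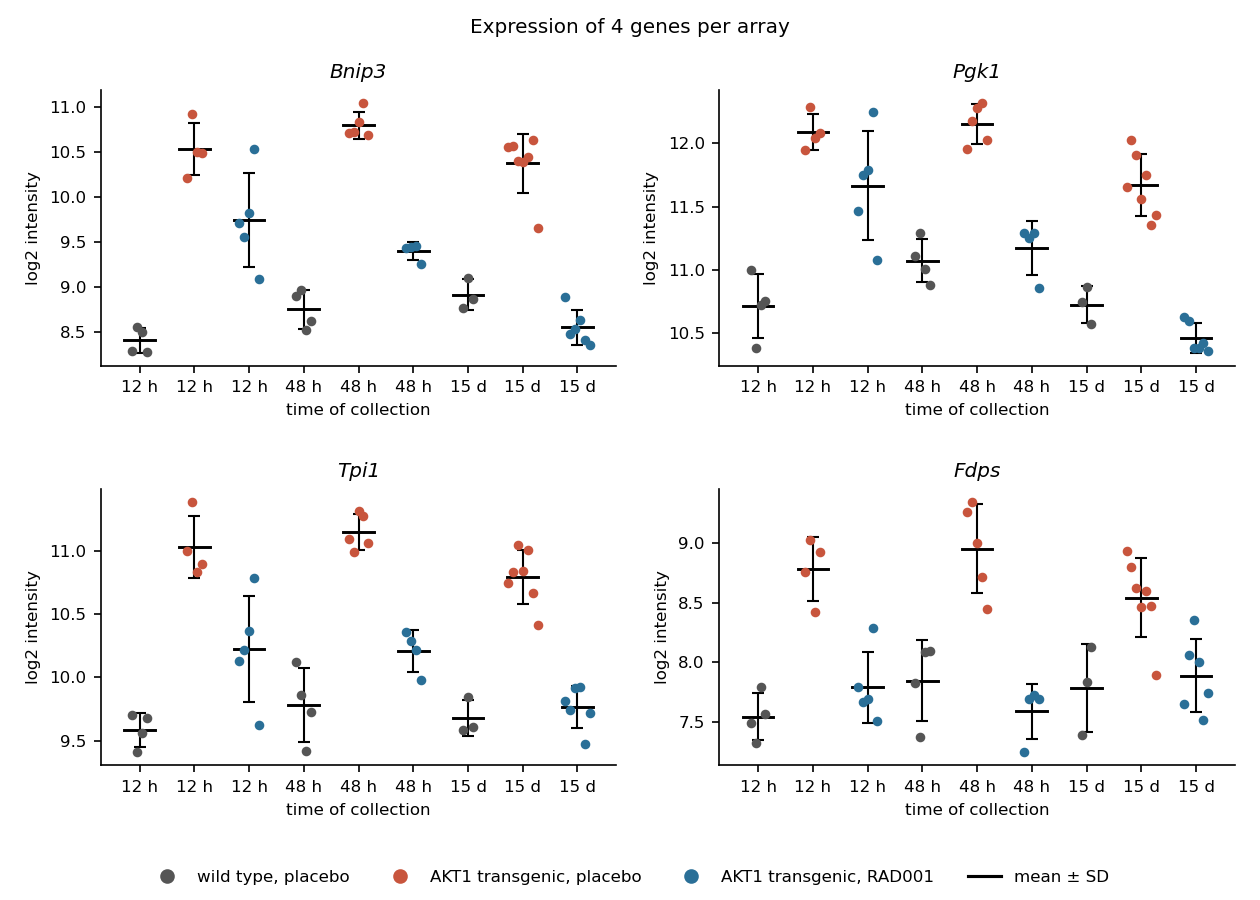
Each point is the log2 intensity of 1 array for Bnip3, Pgk1, Tpi1 and Fdps, grouped by time of collection and by genotype and treatment; black bars are the mean and SD of the group. Bnip3 averaged 10.38 in transgenic placebo arrays and 8.55 in RAD001 arrays at 15 d, beside 8.91 in wild type.

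RAD001 at 15 d gave the late effect of the drug. Glycolytic and hypoxia-responsive genes were lower. Lysosomal genes were lower and smooth muscle, fibroblast, basal epithelial, ribosomal protein and MHC class II genes higher as lists whose calls did not hold with an estimated correlation (adjusted p = 0.0573 to 0.306). Bnip3 was 3.56-fold lower (-1.83 ± 0.15) and lay below the placebo mean in 6 of 6 arrays. Ero1a fell by 1.63 ± 0.25, Tesc by 1.33 ± 0.29 and Gusb by 1.29 ± 0.22. Igbp1, a phosphatase-binding protein gene, fell by 1.79 ± 0.20, although another of its probe sets gave 0.06. Ddit4, which encodes the mTOR inhibitor REDD1, was 6.62-fold higher (2.73 ± 0.65) and the glycogen phosphorylase gene Pygl was 3.78-fold higher (1.92 ± 0.31).

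Of 14 glycolysis genes 8 fell and 0 rose at 15 d (9 fell and 1 rose adjusted over the list alone), with a median of -0.46. Pgk1 fell by 1.21 ± 0.13, Aldoc by 1.21 ± 0.14, Tpi1 by 1.03 ± 0.13 and Aldoa by 0.72 ± 0.12. Of 18 hypoxia targets 5 fell and 1 rose (6 and 2 adjusted over the list alone), with Plod2 at -0.60 ± 0.11. Of 21 lysosome and autophagy genes 5 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0573 with an estimated correlation). The galactosidase gene Gla fell by 0.77 ± 0.14, Hexa by 0.75 ± 0.14, the cathepsin gene Ctsl by 0.53 ± 0.13 and Lamp2 by 0.51 ± 0.08, with probe sets of Lamp2 from -0.77 to 0.02. Androgen-regulated genes were not called as a list by camera (adjusted p = 0.0986), with 3 of 17 lower and 0 higher (4 and 1 adjusted over the list alone). The protease gene Tmprss2 fell by 0.98 ± 0.19, Azgp1 by 0.62 ± 0.14 and the immunoglobulin receptor gene Pigr by 0.41 ± 0.09. Fatty acid synthesis was not called either (adjusted p = 0.236), with 4 of 11 lower and 1 higher, the same as adjusted over the list alone. The acetyl-CoA synthetase gene Acss2 fell by 0.63 ± 0.09 (another probe set gave -0.02) and the desaturase gene Fads1 rose by 0.46 ± 0.08. Cholesterol synthesis had 3 of 19 members lower and 0 higher (5 and 3 adjusted over the list alone), Cyp51 (-1.05 ± 0.27), Fdps (-0.65 ± 0.17; adjusted p = 0.0575 without RAD001 replicate 6) and Fdft1 (-0.60 ± 0.18; 0.131 without the same array). This list was not called (adjusted p = 0.577), and its median of -0.07 and test pointed down while its mean was 0.03.

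Stromal and other cell type markers shifted at the same time. Of 13 smooth muscle genes 5 rose and 0 fell (7 rose adjusted over the list alone), with a median of 0.39 and a score above the placebo mean in 5 of 6 arrays (adjusted p = 0.203 with an estimated correlation). Flna rose by 0.90 ± 0.17, Cnn1 by 0.93 ± 0.24, Tagln by 0.63 ± 0.13 and Acta2 by 0.57 ± 0.11. Of 15 fibroblast genes 2 rose (4 adjusted over the list alone; adjusted p = 0.306 with an estimated correlation), Dcn by 0.70 ± 0.15 and the growth factor receptor gene Pdgfra by 0.55 ± 0.16 (adjusted p = 0.102 without RAD001 replicate 6). Of 11 basal genes 2 rose, the same as adjusted over the list alone (adjusted p = 0.21 with an estimated correlation), Trp63 by 0.47 ± 0.11 and the laminin gene Lamb3 by 0.45 ± 0.11. Of 24 ribosomal protein genes 2 rose (3 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation), Rps9 by 0.48 ± 0.08 and Rps19 by 0.29 ± 0.08 (adjusted p = 0.0707 without RAD001 replicate 6). Of 4 MHC class II genes 1 rose, the same as adjusted over the list alone (adjusted p = 0.262 with an estimated correlation), the invariant chain gene Cd74 by 0.55 ± 0.17 (adjusted p = 0.119 without placebo replicate 8).

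At 15 d limma with Benjamini-Hochberg adjustment called 556 of 9627 features, 242 higher and 314 lower, and 43 by at least 2-fold. Array weights gave 337 and the compared groups alone 192. Of 41 named genes called 9 lost the call without some single array, and 34 lost it or changed sign in some other alternative. The transgenic arrays of this time fell into a set of 4 (replicates 1 and 2 of both treatments, set A) and a set of 9 (set B), which parted along the first principal component. With the array set as a block the median of glycolysis was -0.46, and within sets A and B it was -0.98 and -0.42. The array set as a block called 772 features (362 higher, 410 lower) and set B alone 541 (282 and 259, so that most were higher). Set A alone called 44 features, and there Pygl (-0.09), Nme1 (-0.45) and Rac3 (0.25) had the opposite sign to their change over all arrays. The cholesterol list had a median of -0.44 in set A (called down) and 0.24 in set B (not called). Leaving out placebo replicates 8 and 9, which had 835 and 1092 values at exactly 0, gave 337 features, called the cholesterol list down (adjusted p = 0.0104; 0.271 with an estimated correlation) and ended the calls of Ddit4 (2.07, adjusted p = 0.0806), Nme1 (1.66, 0.185), Fcgbp (1.61, 0.128), Saa2 (-2.08, 0.101) and Cyp51 (-0.74, 0.121). Over all arrays Nme1, a nucleoside diphosphate kinase gene, rose by 2.62 ± 0.71 (adjusted p = 0.0593 without placebo replicate 8; another probe set gave -0.30), and Fcgbp, a mucus protein gene, rose by 2.18 ± 0.57. The GTPase gene Rac3 fell by 2.22 ± 0.38 and Saa2 fell by 2.10 ± 0.64 (adjusted p = 0.171 without RAD001 replicate 6). Akt1 (0.04 ± 0.11), Mtor (0.50 ± 0.36), Eif4ebp1 (-0.05 ± 0.14), Pbsn (-0.19 ± 0.21) and Vegfa (-0.12 ± 0.11) were not called. With all probe sets tested apart, 1 of 2 was called for Vegfa (-1.01 to -0.12). The Mtor value includes placebo replicate 9 at the floor of 4.0 (nearest array 7.74), and the other probe set of Mtor gave -0.01. Slc2a1 was at 0.11 ± 0.39 over all arrays and fell by 0.48 without the arrays with many zeros (adjusted p = 0.00332). Tested apart, 1 of the 3 probe sets of Slc2a1 was called (-1.16 to 0.11).

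**Figure D2:**
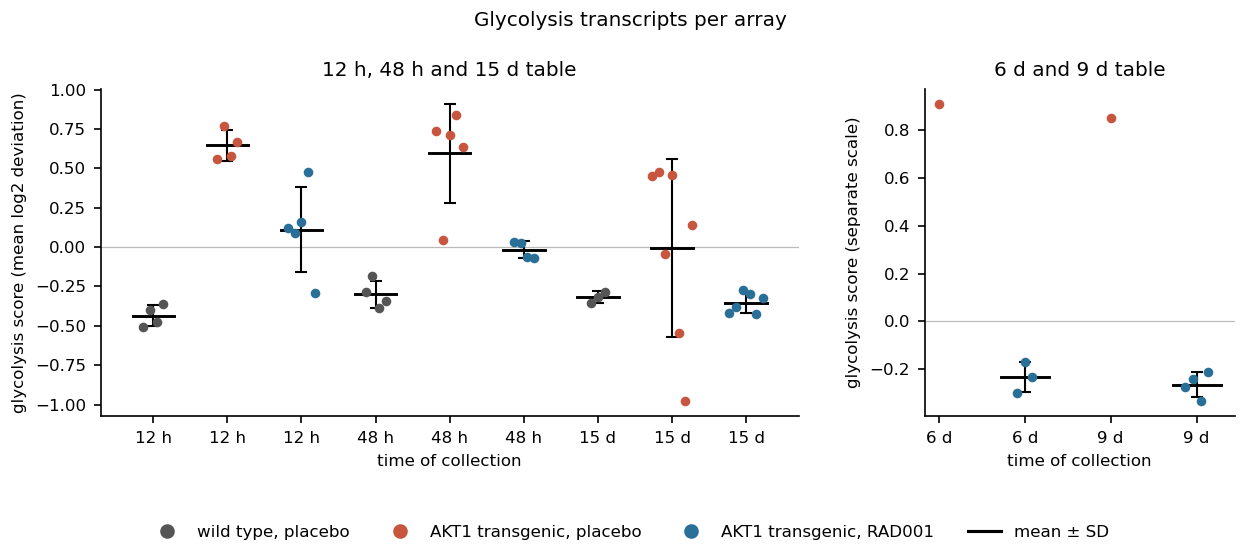
Each point is the glycolysis score of 1 array, the mean log2 deviation of the measured members from their mean over the table, by time of collection, with the 12 h, 48 h and 15 d table on the left and the 6 d and 9 d table, on its own scale, on the right; black bars are the mean and SD. At 48 h the score averaged 0.60 in transgenic placebo, -0.02 in RAD001 and -0.30 in wild type arrays, and at 15 d placebo replicates 8 and 9 lie at -0.55 and -0.98, below every RAD001 array.

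RAD001 at 6 d and 9 d was tested as the mean of both days against 1 placebo array per day, so the lone placebo arrays are assumed to vary like the other groups. Glycolytic, hypoxia-responsive, cholesterol synthesis and lysosomal genes were lower. Of 13 glycolysis genes 9 fell (12 adjusted over the list alone) and 0 rose, with a median of -1.12. Pgk1 fell by 1.65 ± 0.07, the lactate dehydrogenase gene Ldha by 1.32 ± 0.09, Aldoc by 2.17 ± 0.18 and Tpi1 by 1.12 ± 0.09. Bnip3 was 4.94-fold lower (-2.31 ± 0.15), and in 3 of 3 arrays on day 6 and 4 of 4 on day 9 it lay below the placebo array of the day.

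Of 16 hypoxia targets 4 fell (5 fell and 1 rose adjusted over the list alone). Ddit4 fell by 2.67 ± 0.15, opposite to its change at 15 d, Ero1a fell by 1.75 ± 0.16 and the mitochondrial protein gene Higd1a by 0.93 ± 0.16 (adjusted p = 0.1 without 9 d RAD001 replicate 1). In cholesterol synthesis 4 of 19 fell and 0 rose (10 fell adjusted over the list alone), with a median of -0.74. Fdps fell by 1.21 ± 0.14, Dhcr7 by 1.38 ± 0.22, Msmo1 by 1.25 ± 0.21 and the isomerase gene Idi1 by 1.22 ± 0.19. Without 6 d RAD001 replicate 3 the adjusted p of Dhcr7 was 0.088 and that of Msmo1 0.114, and without 9 d RAD001 replicate 4 that of Idi1 was 0.0809. Of 11 fatty acid synthesis genes 1 fell, the same as adjusted over the list alone (adjusted p = 0.309 with an estimated correlation), the desaturase gene Scd2 by 0.87 ± 0.14 (adjusted p = 0.0984 without 6 d RAD001 replicate 3). Of 21 lysosomal genes 1 fell (8 adjusted over the list alone), the sialidase gene Neu1 by 1.4 ± 0.20 (adjusted p = 0.0661 without 6 d RAD001 replicate 3). Stromal and basal lists were called up. Smooth muscle genes had a median of 0.38 with 0 of 14 passing (6 rose adjusted over the list alone; adjusted p = 0.306 with an estimated correlation). Of 15 fibroblast genes 1 rose, the same as adjusted over the list alone (adjusted p = 0.444 with an estimated correlation), Dcn by 0.58 ± 0.09 (adjusted p = 0.0881 without 6 d RAD001 replicate 3). Basal genes had a median of 0.37 with 0 of 10 passing (2 rose adjusted over the list alone; adjusted p = 0.262 with an estimated correlation).

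At 6 d and 9 d limma with Benjamini-Hochberg adjustment called 83 of 9345 features, 31 higher and 52 lower, and 45 of them changed by at least 2-fold. Array weights gave 188, and the replicate number as a block gave 5 (2 higher, 3 lower), although the numbers were not taken as pairs. Of 24 named genes called 11 lost the call without some single array, and 22 lost it or changed sign in some other alternative. Day 6 alone gave 14 and day 9 alone 28. Leaving out 1 array gave 39 features (6 d RAD001 replicate 1), 34 (6 d replicate 3), 43 (9 d replicate 1) or 50 (9 d replicate 4). The interferon-induced gene Rsad2 rose by 3.79 ± 0.37, and another of its probe sets gave 0.24. The metallothionein gene Mt3 rose by 3.0 ± 0.20 and the ER nucleotide exchange gene Sil1 by 2.82 ± 0.12, but on day 9 alone their values were 0.10 and -0.08. The arginase gene Arg1 fell by 3.03 ± 0.44 (adjusted p = 0.0584 without 9 d RAD001 replicate 1), the pyruvate kinase gene Pklr by 1.68 ± 0.18, the transferrin receptor gene Tfrc by 1.87 ± 0.29 (0.088 without 6 d RAD001 replicate 3) and Fam3b by 1.85 ± 0.23. Akt1 (-0.06 ± 0.10), Mtor (0.09 ± 0.14), Eif4ebp1 (-0.26 ± 0.14), Pbsn (0.05 ± 0.15), Slc2a1 (-0.72 ± 0.21) and Vegfa (1.57 ± 0.30; another probe set -1.26) were not called.

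Across the comparisons, glycolysis was called up in transgenic glands and down in each of the 4 comparisons of RAD001 with placebo, and these calls held with an estimated correlation (adjusted p = 0.00285 to 0.00301). The hypoxia list did the same, except that at 12 h its call did not hold (0.0675), with 0.0265 at 6 d and 9 d and 0.00285 elsewhere. Besides these, the calls that held were smooth muscle (adjusted p = 0.0477) and lysosome (0.0143) for the genotype, cholesterol synthesis (0.0493) and the clock (0.0267) at 12 h, cholesterol synthesis (0.0121) and lysosome (0.0373) at 48 h, and cholesterol synthesis (0.0435) and lysosome (0.0196) at 6 d and 9 d. In each called list the median, mean and test had the same sign.

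**Figure D3:**
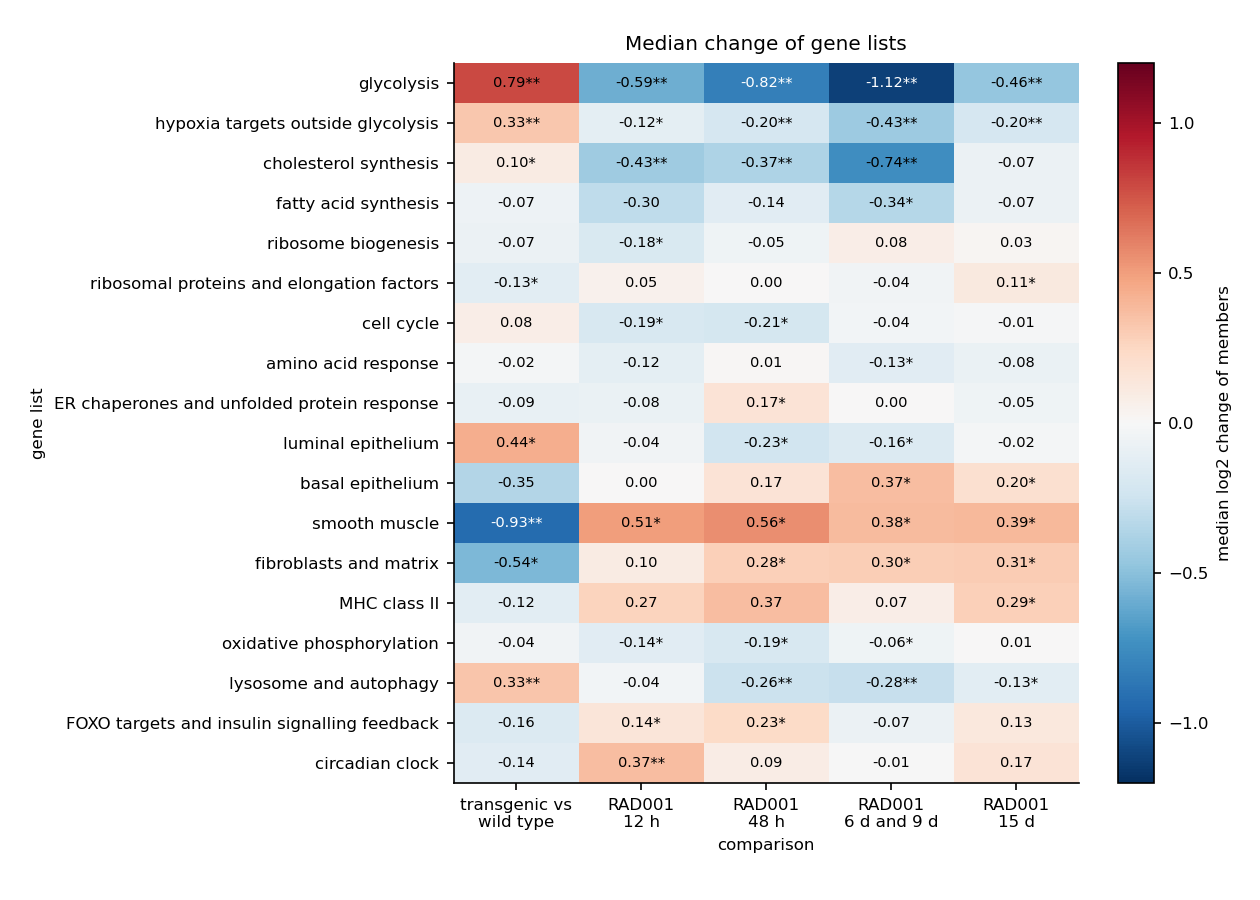
Each cell gives the median log2 change of the measured members of a list (vertical axis) in a comparison (horizontal axis), in colour and as a number; 1 asterisk marks a camera call at an adjusted p under 0.05 and a pair marks a call that also held with an estimated correlation. Glycolysis runs from 0.79 in the genotype comparison to -0.59, -0.82, -1.12 and -0.46 with RAD001 at 12 h, 48 h, 6 d and 9 d, and 15 d.

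Whether the RAD001 effect differed between 12 h, 48 h and 15 d was tested directly, and 48 features passed the F-test of limma with Benjamini-Hochberg adjustment. The tubulin genes Tubb5 (-0.42 ± 0.10, -0.11 ± 0.10 and 0.66 ± 0.08 at 12 h, 48 h and 15 d; adjusted p = 4.63e-06) and Tubb4b (-0.95, -0.50 and 0.62; 0.000266) were among them. Pcna had effects of -0.75, -0.42 and 0.33 (0.000308). Clu, which encodes the chaperone clusterin, had effects of 0.13, 0.12 and -1.23 (0.000984), and Lamp2 of 0.19, -0.47 and -0.51 (0.00381). Leaving out 1 array gave 29 features (12 h placebo replicate 2), 31 (12 h placebo replicate 3), 28, 26 or 27 (12 h RAD001 replicate 1, 2 or 3), 21 (15 d RAD001 replicate 4) or 28 (15 d RAD001 replicate 6). The set of 15 d arrays as a block gave 104 features, and leaving out set B gave 12. Of 100 splits of the arrays within each time, the real one included, 5 gave as many features. Between 12 h and 15 d the effect on the cholesterol synthesis and ribosome biogenesis lists moved up (adjusted p = 0.0295 each) and that on the lysosome list moved down (0.0104), and none of these held with an estimated correlation (adjusted p = 0.373 each). Within set A the adjusted p for the cholesterol list was 0.699 and within set B 0.00365.

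The genotype difference also varied between the times, with 1967 features past the same F-test. Strap, which encodes a protein of RNA-binding complexes, was higher at 12 h and 48 h (1.39 ± 0.13 and 1.05 ± 0.13) and at -0.13 ± 0.13 at 15 d. Gtpbp2 was at -0.15, 0.70 and -0.55, the immune receptor gene Nfam1 at -2.34, -0.81 and -0.53, Stambp at 0.51, 1.13 and -0.45, and Pdzd11 at 1.12, -0.45 and 0.66. Without wild type 15 d replicate 1 the count was 999, without the 15 d arrays of set B 900, and with the array set as a block 964.

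A group of 12 named genes was called in the same direction with RAD001 at 12 h, 48 h and 15 d. Lower at all times were the glycolysis genes Aldoa, Hk2, Pfkl and Tpi1, the hypoxia target Bnip3, Fdps, Psat1 and Fam3b. Higher were Fbxo32 (1.28, 1.12 and 1.0), the translation initiation factor gene Eif3f (0.43, 0.46 and 0.35), the chromatin protein gene Phf1 (0.68, 0.87 and 0.53) and the signal recognition particle gene Srp68 (0.54, 0.72 and 0.46). Eif3f, Phf1 and Srp68 stand outside the rule for named genes and were chosen after their values were seen. Of the features called at 12 h and at 48 h, 42 went the same way, where 2.47 would be shared by chance. For 12 h and 15 d the shared count was 29 against 4.17, and for 48 h and 15 d 92 against 9.67. These chance figures take genes as independent. The 3 times also share 1 estimate of the spread per gene, so the figures may be too low. The calls at 6 d and 9 d shared 8, 22 and 34 features with those at 12 h, 48 h and 15 d, against 0.696, 1.54 and 2.63.

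The last comparison asked whether RAD001 moved the transcripts that the transgene had changed back towards wild type. The genotype genes were called from the other times, so that no array entered both effects. At 12 h 63.4% of 1972 genotype genes had a RAD001 change of the opposite sign, at 48 h 64.8% of 2636 and at 15 d 64.1% of 4002. Genes called with RAD001 in the opposite direction numbered 51, 180 and 340, and genes called further in the direction of the transgene 13, 19 and 45. Bnip3, Pgk1, Tpi1 and Ero1a were among those that were higher with the transgene and fell with RAD001 at 15 d, and Tagln, Dcn and Flna were lower with the transgene and rose. Of 100 splits of the arrays of a time into groups of the same sizes, the real one included, 25, 4 and 7 gave a share as large at 12 h, 48 h and 15 d. The correlation of both effects across genes, which are not independent replicates, was -0.33, -0.47 and -0.30, and 27, 2 and 3 of these splits gave one as low.

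**Figure D4:**
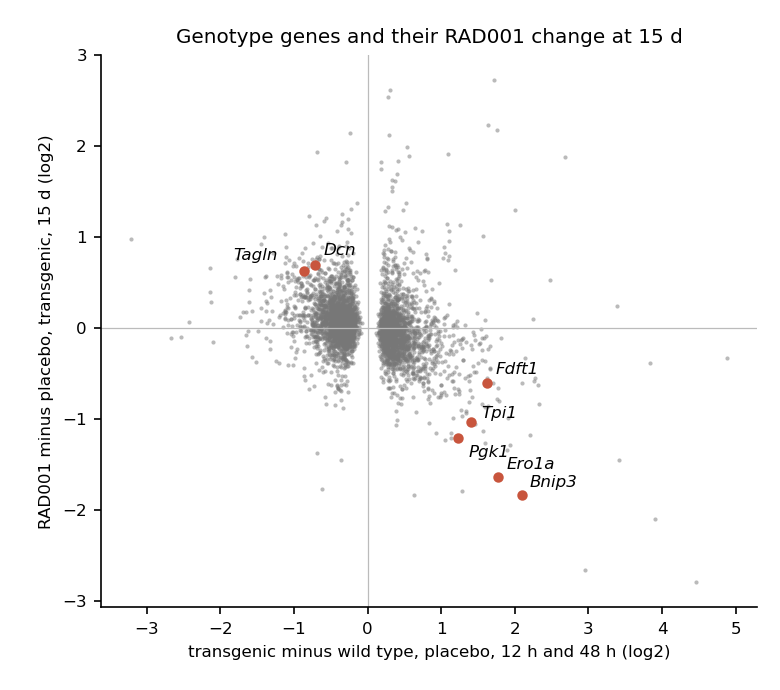
Each point is 1 of 4002 genes called between transgenic and wild type placebo arrays at 12 h and 48 h; the horizontal axis gives that difference and the vertical axis the change with RAD001 at 15 d, both in log2. Bnip3, Ero1a, Pgk1, Tpi1 and Fdft1 lie at the lower right and Tagln and Dcn at the upper left, and 64.1% of the points lie in the quadrants of opposite sign.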

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

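The tests without the arrays with many zeros, the difference between the glycolysis and luminal scores, the tests of the genotype difference over time, the splits for genotype genes moved back, the place of the array sets in the 15 d splits and the tests of lists within an array set were chosen only after the result was seen.

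The response of glycolysis to RAD001 came with a rise of smooth muscle genes, so that a lower share of epithelium in treated glands is a candidate explanation. Against it, the glycolysis score fell by 0.43 log2 more than the luminal epithelial score over 12 h, 48 h and 15 d (-0.57, -0.42 and -0.31; permutation p = 6e-05, two-sided, 100000 resamples). With the stromal score of each array as a covariate the median glycolysis change at 15 d was -0.47 (SE 0.23 over members) beside -0.46 without it, only just beyond 2 SE, while the features called went from 556 to 330. At 48 h the same covariate took them from 341 to 69 and the glycolysis genes called from 8 to 4, with a median of -0.71 after -0.82. A lower share of epithelium as the whole cause is therefore not what the luminal list as a mean shows for glycolysis. Krt8, the only luminal gene of 18 called at 12 h and 48 h, did fall, with probe sets at -0.65 to -0.60 and -0.71 to -0.67. Whether the luminal markers follow the cells that carry the glycolysis transcripts was not tested, so this explanation is not excluded. The SE over members is not a spread between arrays. For other genes a change of cell composition stays open as well.

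The transgenic arrays of 15 d fall into sets of 4 and 9 with both treatments in each. The sets were cut at the largest gap of the first principal component among arrays without many zeros. Without the arrays with many zeros 3573 genes were called between the sets, and 2960 with them. A difference without those arrays was thus built into the cut, so these counts do not test whether they account for the sets. For the share of stroma, the smooth muscle list differed by -0.18 (SE 0.11 over members), with 0 of 13 members higher and 1 lower in set B. Called genes differed by 0.47 at the median, but they were picked for differing between the sets. This comparison therefore does not exclude the share of stroma as a part of the cause. A difference in handling may lie behind the sets, but the labels give no batch, and no biological explanation other than the share of stroma was tested. Of 100 splits of the 15 d arrays, the real one included, 3 called as many features as RAD001 and placebo (556), and the other 2 (1209 and 749) put all 4 arrays of set A in 1 arm. A further split called 510 features, with 2 arrays of set A in each arm and both arrays with many zeros in 1 arm. The real split has the same layout, with both of these arrays under placebo. Other splits of this layout called 77 features or fewer.

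The genotype difference changed between times for 1967 features by the F-test (999 without wild type 15 d replicate 1). Without the 15 d arrays of set B 900 passed, and all 3 wild type arrays of 15 d lie with set A, so the sets could add to the count without being its only source. Wild type placebo arrays differed between 12 h and 48 h in 1650 genes (median 0.54), and transgenic placebo arrays changed these by -0.01 in the same direction (SD 0.15) and gave 0 calls (486 at an unadjusted p under 0.05, with 481 expected by chance), which argues against a difference in handling of 12 h and 48 h shared by both genotypes. For the wild type arrays alone time and handling cannot be told apart, because each time has its own arrays and the labels give no batch. A change of the genotype difference with age or duration of placebo was not tested.

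The effect of RAD001 differed between 12 h, 48 h and 15 d for 48 features, and chance cannot be excluded for this count, since other splits called up to 263. Between 12 h and 15 d the effects on cholesterol synthesis and ribosome biogenesis (adjusted p = 0.0295 each) and on lysosomal genes (0.0104) differed, by 0.50, 0.21 and -0.21 at the median, and none held with an estimated correlation (adjusted p = 0.373 each). Within set A the adjusted p was 0.699, 0.203 and 0.00124, and within set B 0.00365, 0.0353 and 0.0301.

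Single arrays stood apart from their group by a test of the largest gap in 11 of 126 groups and measures, where chance gives about 1 in 20. Transgenic placebo replicate 4 of 48 h was low for Akt1 (9.32, nearest 9.68) and high for Slc2a1 (9.41, nearest 8.94). Transgenic placebo replicate 9 of 15 d was at the floor of 4.0 for Mtor (nearest 7.74) and for Slc2a1 (nearest 8.16), and replicate 10 was low for Bnip3 (9.66, nearest 10.38). RAD001 replicate 5 of 48 h was low for Bnip3 (9.25, nearest 9.43) and Pgk1 (10.86, nearest 11.25), and replicate 1 was low for Fdps (7.24, nearest 7.69). At 9 d RAD001 replicate 3 was high for Vegfa (8.34, nearest 7.46) and replicate 1 for Bnip3 (8.24, nearest 8.02). The glycolysis score of transgenic placebo replicate 2 of 48 h was 0.05, with the nearest at 0.64.

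Chance is taken as excluded where under 5 of 100 splits of the arrays within each time, the real one included, give a result as large. For features called only the real split did so for the genotype effect (3222, highest other 1036), RAD001 at 12 h (142 and 136) and RAD001 at 48 h (341 and 260). For the genotype effect by time (1967, highest other 860) the splits mix the genotypes, which removes the genotype difference itself. They therefore do not test whether that difference changes with time, and no conclusion on chance is drawn for it. The overlaps of RAD001 calls were 42, 29 and 92, with a highest other of 0 each. A shared feature needs calls at both times, and most relabelled splits of 15 d called few features or none. These splits therefore cannot tell an overlap beyond chance from the counts of calls, and no conclusion is drawn from them. For called lists, adjusted within the comparison, chance is excluded at 12 h with 3 splits (9 lists, highest other 9) and at 15 d with 2 (8 and 10), but not for the genotype (8 and 9) or at 48 h (12 and 15), with 5 splits each. For genotype genes moved back, 4 splits were as large at 48 h (64.8%, highest other 71%), which passes this limit only narrowly. The limit makes no allowance for the several times and both measures tried, so chance is not firmly excluded there. It is not excluded at 12 h with 25 splits (63.4% and 80%) or at 15 d with 7 (64.1% and 71.6%). By the correlation of both effects, 27 splits were as low at 12 h (-0.33, lowest other -0.65), 2 at 48 h (-0.47 and -0.49) and 3 at 15 d (-0.30 and -0.32), so at 15 d the share and the correlation fall on different sides of this limit.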

How the results depend on the processing

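The alternatives without arrays with many zeros, those using the 15 d array sets and the genotype effect from 12 h and 48 h only were chosen after seeing the data, and the others were planned. The number of arrays and, for dim probe sets, the signal over background limit every result. For named genes and lists 318 results were refitted 7172 times. Of these fits 6532 kept direction and side of the threshold, 463 lost a call, 138 gained one, 7 had the opposite sign in a called value and 32 moved an uncalled value. All named genotype calls but 2 of 48 held in every alternative, beside 7 of 22 at 12 h, 21 of 31 at 48 h, 7 of 41 at 15 d and 2 of 24 at 6 d and 9 d. The cause of the changes was not tested unless stated.

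Array weights gave 857 features for RAD001 at 12 h, 578 at 48 h, 337 at 15 d and 188 at 6 d and 9 d, 162 for the RAD001 effect by time, 3063 for the genotype effect by time, and overlaps of 206 (12 h and 48 h) and 73 (12 h and 15 d). Fits of the compared groups only, which have fewer arrays to estimate the spread, gave 78 at 12 h, 192 at 15 d and 24 by time. The replicate number as a block gave 319 at 15 d, 5 at 6 d and 9 d and 1043 for the genotype by time. Arrays with the same number were no closer than others at 12 h and 48 h, where the correlations of their residuals ran from -0.08 to 0.05, and at 15 d they ran from -0.01 to 0.48 between placebo and RAD001. The mean at 15 d was 0.23 for shared numbers and -0.02 for others, numbers 1 and 2 lie in set A in both treatments, and 0 of 4 arrays correlated best with their own number. The numbers were not taken as pairs, since not every pair was correlated. Day 6 alone gave 14 features and day 9 alone 28, with fewer arrays. At an unadjusted p under 0.01 the overlaps were 135, 106 and 186.

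Without the arrays with many zeros the counts were 232 at 12 h and 337 at 15 d, and the overlap of 12 h and 48 h was 73. The 15 d array set as a block gave 104 features for RAD001 by time and 964 for the genotype by time, and leaving out set B gave 12 and 900. Set A alone gave 44 features for RAD001 at 15 d, from 4 arrays. Genotype and RAD001 effects of the same time with the placebo arrays split moved back 74.3% at 12 h, 76.8% at 48 h and 84.4% at 15 d. Both parts of the placebo arrays belong to the same group, so a shift shared by that group enters the effects with opposite sign. At 15 d each part held an array with many zeros. These shares were not set against other splits and are not read as a larger return towards wild type. With an estimated correlation 4 lists were called for the genotype, 3 at 12 h, 4 at 48 h, 2 at 15 d and 4 at 6 d and 9 d, and fry called 14 for the genotype and 5 at 6 d and 9 d.

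Leaving out 1 array at a time gave from 2910 to 3424 features for the genotype, 31 (12 h placebo replicate 2) to 175 (12 h RAD001 replicate 4) at 12 h, 147 (48 h RAD001 replicate 5) to 398 (48 h placebo replicate 1) at 48 h, 372 to 719 at 15 d and 34 (6 d RAD001 replicate 3) to 112 (9 d RAD001 replicate 3) at 6 d and 9 d. For the RAD001 effect by time the range was 21 (15 d RAD001 replicate 4) to 71 (48 h placebo replicate 1) and for the genotype by time 999 (wild type 15 d replicate 1) to 2619 (transgenic placebo 15 d replicate 2). Genotype genes moved back ranged from 54.7% to 70.3% at 12 h, 60.6% to 69.0% at 48 h and 61.2% to 67.5% at 15 d.

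Slc2a1 at 15 d (0.11, not called) was -0.50 with the replicate block (adjusted p = 0.0168), -0.48 without the arrays with many zeros (0.00332), and from -0.51 without placebo replicate 9, which holds it at the floor (0.000782), to 0.24 without placebo replicate 8. In set A alone Pygl was -0.09, Nme1 -0.45 and Rac3 0.25, and on day 9 alone Sil1 was -0.08. The share of called features that were higher shifted by over 10 points in these alternatives. At 12 h these were median scaling (34 higher, 124 lower), array weights (513 and 344, so that most were higher) and leaving out placebo replicate 1 (most lower), placebo replicate 3 or RAD001 replicate 4 (most higher for both). At 15 d it was set A alone (7 and 37), and at 6 d and 9 d no filter on dim probe sets (29 and 86), median scaling (34 and 35) and day 9 alone (15 and 13). At 48 h, with a shift under 10 points, most were lower with the compared groups only (110 higher, 123 lower) and without RAD001 replicate 5 (69 and 78). At 15 d most were higher with set B alone (282 higher, 259 lower), also with a shift under 10 points. A fit of the compared groups only or without a lone placebo array was not run for 6 d and 9 d, since the first is the whole table and the second leaves a day without a control.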

Other observations

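The lists and tests of this part were fixed beforehand. At 48 h of RAD001 the ER chaperone list was called up with 2 of 22 members passing (3 adjusted over the list alone), a median of 0.17 and an adjusted p = 0.021 (adjusted p = 0.595 with an estimated correlation). The members were Dnajb9, a co-chaperone induced by the unfolded protein response, which rose by 1.25 ± 0.27, and Derl3, a gene of ER-associated degradation, which rose by 1.23 ± 0.29 (adjusted p = 0.0518 without RAD001 replicate 5). The values of the ubiquitin ligase gene Syvn1 (0.61 ± 0.18) and of Manf (0.51 ± 0.20) did not pass. At 6 d and 9 d the amino acid response list was called down with 0 of 21 members passing (1 fell adjusted over the list alone), a median of -0.13 and an adjusted p = 0.0148 (adjusted p = 0.149 with an estimated correlation). Oxidative phosphorylation was called down there as well, with 0 of 25 members passing in either adjustment and a median of -0.06 (adjusted p = 0.322 with an estimated correlation). The luminal list was called down with a median of -0.16 (adjusted p = 0.491 with an estimated correlation). Its 1 member past the threshold over all genes was higher, the keratin gene Krt4 (1.51 ± 0.24; adjusted p = 0.0702 without 9 d RAD001 replicate 4), and adjusted over the list alone 1 rose and 1 fell.

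Markers of immune and vascular cells gave no list call by camera in any main comparison in which they were tested, with adjusted p from 0.47 to 0.98 for macrophages, 0.83 to 0.941 for T cells, 0.63 to 0.969 for B and plasma cells, 0.378 to 0.941 for neutrophils, 0.469 to 0.977 for endothelium and 0.236 to 0.881 for the interferon response. Camera also gave no call for skeletal muscle (0.536 to 0.969), apoptosis and p53 targets (0.108 to 0.831) and immediate early and heat shock genes (0.103 to 0.965). The calls of fry included skeletal muscle down (adjusted p = 0.00428) and immediate early and heat shock genes up (0.00364) for the genotype. They also included apoptosis and p53 targets up at 12 h of RAD001 (adjusted p = 0.0366). The lowest adjusted p of camera for adipocyte genes was 0.0812 at 15 d of RAD001, with a median of 0.49 and 1 of 6 higher in both adjustments. MHC class II genes had a median of 0.27 at 12 h and 0.37 at 48 h of RAD001 without a call by camera (adjusted p = 0.0739 and 0.0546). The list of seminal vesicle and other lobe genes had too few measured members to be tested in either table, and that of B and plasma cells had too few at 6 d and 9 d. Median, mean and test differed in sign for some lists that camera did not call, such as androgen-regulated genes (median -0.15, mean 0.06, test up) and the interferon response (-0.09, 0.20, up) between genotypes.

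In transgenic placebo replicates 8 and 9 of 15 d the glycolysis scores of -0.55 and -0.98 lay below the wild type mean of -0.32 ± 0.04 (SD, n = 3), while Bnip3 was above every wild type array of that time in 7 of 7 transgenic placebo arrays.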
